A study of Homo sapiens with 6 samples.

How the data were processed

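Total RNA from 6 cultures of HEK293DYG cells was measured on Affymetrix Human Gene 1.0 ST arrays, 1 array per culture. HEK293DYG is a human embryonic kidney line of the T-REx type, which makes the tetracycline repressor, and it carries a green fluorescent protein under tetracycline control and a yellow fluorescent protein fused to dihydrofolate reductase (DHFR.YFP). Per the labels, 3 cultures received DMSO (vehicle) and 3 received doxycycline at 1 µg/mL with trimethoprim at 10 µM, each for 12 h. RNA was isolated on silica columns with DNase digestion on the column, and 200 ng per sample entered a whole-transcript amplification, per the labels' protocols. The design text states that the replicates were biological.

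The deposited values are log2 expression values per probe set, made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, gives all arrays one common distribution and summarises the probes of a probe set into a single value. The version of RMA, the summary level, any filter on probe sets, and the slide and scan dates are not given in the sources used here. The log2 scale was read from the values, which ran from about 4 to 14 on each array. The scanner files were not used here, so no detection call against background was made.

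The table held 22148 probe sets. The platform annotation paired 19129 of them with 1 gene symbol, 1735 with several and 1284 with none. Of those with 1 symbol, 19099 matched a current gene through their Entrez identifier in a RefSeq gene table for the assembly GRCh38.p14, and no symbol needed an update (0 changed); 30 did not match and kept the annotation's symbol. Where a gene had several probe sets, as 626 genes did, the probe set with the highest mean over the 6 arrays stood for it, which left 18276 genes. A probe set with several symbols named no gene, and its results stand apart from the gene test. No genome build is named in the labels, so no positions are given; the RefSeq table served for names, biotypes, the length of a gene's span and which genes neighbour each other.

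Genes were tested with limma version 3.58.1 in R version 4.3.3, with lmFit and plain eBayes on the deposited log2 values of all 6 arrays, 2-sided, treated minus vehicle, with no covariate. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was an adjusted p under 0.05. No filter on dim probe sets was applied. The fit had 4 residual and 6.14 prior degrees of freedom. Standard errors are the moderated ones of limma, and intervals are 95% intervals from the same fit. Fold values are 2 raised to the log2 difference.

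Before the data were examined, 31 gene lists were fixed from general knowledge of pathways and cell type markers, together with the test, the alternatives and the rule for the genes named. The lists covered the 3 arms of the unfolded protein response (targets of XBP1s, of ATF6, and of PERK and ATF4), other stress responses, mitochondrial genes, folate metabolism, which trimethoprim addresses in bacteria, cell cycle, signalling, the ribosome, small nucleolar RNAs as a sign of RNA preparation, and markers of epithelial, neuronal, fibroblast, leukocyte and endothelial cells. Each of the 30 lists with at least 3 measured members was tested with camera of limma at its preset correlation between genes of 0.01, with adjustment over the lists. Members without a single-gene probe set were left out, among them 6 of 22 cholesterol genes, 6 of 32 cytosolic ribosomal protein genes and 3 of 16 NRF2 targets. The list of 15 genes transcribed from mitochondrial DNA had 0 members with a single-gene probe set and was not tested. Counts of list members past the threshold are given over all genes and adjusted over the list alone. The named genes are the 12 higher and the 12 lower genes with the largest differences among those past the threshold, 12 genes fixed in advance (HSPA5, HSP90B1, PDIA4, DNAJB9, SEL1L, HERPUD1, XBP1, DDIT3, TRIB3, ASNS, DHFR and TYMS), and the 3 members with the smallest p of each list described. DHFR had no single-gene probe set and has no value here.

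The fits were tested on simulated data made from the means and spreads of the 18276 genes, with 200 genes changed in each of 20 simulations. The limma fit recovered 0% of the changed genes at a log2 change of 0.25, 84.2% at 0.5 and 99.1% at 1, and 4.62% of calls at 0.5 and 3.86% at 1 were false. In the same number of simulations, camera called the 21 measured XBP1s targets in 0% without a shift and in 100% at a shift of 0.1 and of 0.2. The simulated genes varied independently, so those shares hold for uncorrelated genes only.

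The labels give both groups the replicate numbers 1 to 3 without saying that a number marks a shared day. The numbers were therefore not treated as pairs, a choice made before the data were examined. The deviations from the group means of arrays with the same number had correlations of -0.08, -0.08 and -0.13. Those of treated and vehicle arrays with different numbers ran from 0.007 to 0.08. The alternatives were eBayes with trend and robust settings, array weights, the mean of a gene's probe sets, every row tested, the dimmer genes left out (those under the median level), the median of each array set to 0, quantile normalization once more, a replicate block, each array left out in turn, other thresholds, and for lists an estimated correlation, ranks and fry. Cyclic loess normalization was added after the data were seen. The number of arrays limits the precision.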

Results

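Expression was profiled in HEK293DYG cells on 6 arrays, 3 from cultures given vehicle (DMSO) and 3 from cultures given doxycycline (1 µg/mL) with trimethoprim (10 µM) for 12 h. Doxycycline switches on tetracycline-controlled transgenes, and trimethoprim, an inhibitor of bacterial dihydrofolate reductase, is used to stabilise proteins fused to that enzyme. The series title concerns the activation of XBP1s and ATF6, transcription factors of the unfolded protein response, by ligands that act on engineered proteins. This line carries fluorescent proteins in place of those factors, so the comparison asks what the ligands and the switched-on fluorescent proteins did to endogenous transcripts. The 6 arrays had medians between 7.93 and 7.96 on the log2 scale. The lowest correlation between arrays over the 18276 genes was 0.999 within the vehicle group and 0.997 within the treated group. The median standard deviation of a gene over replicates was 0.0476 with vehicle and 0.0804 with treatment, so the treated cultures were the more variable group.

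Few transcripts passed the test after treatment, and nearly all of their differences were small. DENND1B, which encodes a guanine nucleotide exchange factor for Rab35, rose 2.03-fold and had the largest change of the 61 genes past the threshold. HMOX1 (heme oxygenase 1) and GCLM (the modifier subunit of glutamate-cysteine ligase, which makes a precursor of glutathione) rose 1.53-fold and 1.54-fold. WDR33, a subunit of the mRNA polyadenylation complex, rose by a log2 difference of 0.59. CGA, the alpha subunit shared by the glycoprotein hormones, fell 1.59-fold. A group of small nucleolar RNAs, which guide the chemical modification of ribosomal and spliceosomal RNA, also passed the threshold, with falls of up to 1.57-fold. None of the fixed marker genes of endoplasmic reticulum stress passed the test.

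In the limma test, 61 of 18276 genes passed an adjusted p of 0.05, 16 higher and 45 lower with treatment. Of these, 4 higher and 4 lower genes differed by at least 1.5-fold. At an unadjusted p under 0.05 there were 3468 genes, where 914 are expected by chance, so the 61 genes do not count the small differences, of which the test recovered 0% in simulations at a log2 change of 0.25. The count depended on single arrays: it was 1 without any one of the vehicle arrays, 2 without treated replicate 1, 278 without treated replicate 2 and 1454 without treated replicate 3. All 61 genes kept their sign in each of these fits, and DENND1B passed in every one of them. The kept signs were nearly fixed in advance, since the genes had been chosen on these same arrays. With array weights, which gave treated replicates 2 and 3 the lowest weights (0.477 and 0.326), 2697 genes passed.

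DENND1B (probe set 7923141) measured 9.15 ± 0.05 with vehicle and 10.17 ± 0.07 with treatment (mean ± SD of log2 values, n = 3 arrays each), a difference of 1.02 with a standard error of 0.0565 and a limma adjusted p of 8.67e-05. A second DENND1B probe set, 7923131, differed by 0.95 (95% interval 0.82 to 1.07). GCLM (probe set 7917779) differed by 0.62 (standard error 0.0693), HMOX1 (probe set 8072678) by 0.61 (0.0675) and WDR33 (probe set 8055060) by 0.59 (0.0628), each with an adjusted p of 0.0119 and each higher on 3 of 3 treated arrays than on any vehicle array. The other genes with the largest rises among those past the threshold were B4GALNT1, a ganglioside synthase, at 0.42, MLLT11 at 0.41, the transcribed pseudogene GABARAPL3 at 0.41, UNKL at 0.40, LILRA1 at 0.34, PDE6B at 0.33, BIN1 at 0.33 and the antisense RNA LY86-AS1 at 0.32, with adjusted p from 0.0236 to 0.0442. The probe sets of UNKL disagreed, since its second one, 7998466, differed by 0.03 (limma adjusted p over all rows of 0.804). GABARAPL3 resembles its parent gene GABARAPL1 closely, so its signal may not be its own. The mean of LILRA1 on vehicle arrays was 5.69, near the low end of the scale, where 3.80 was the lowest value of vehicle replicate 1.

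**Figure D1:**
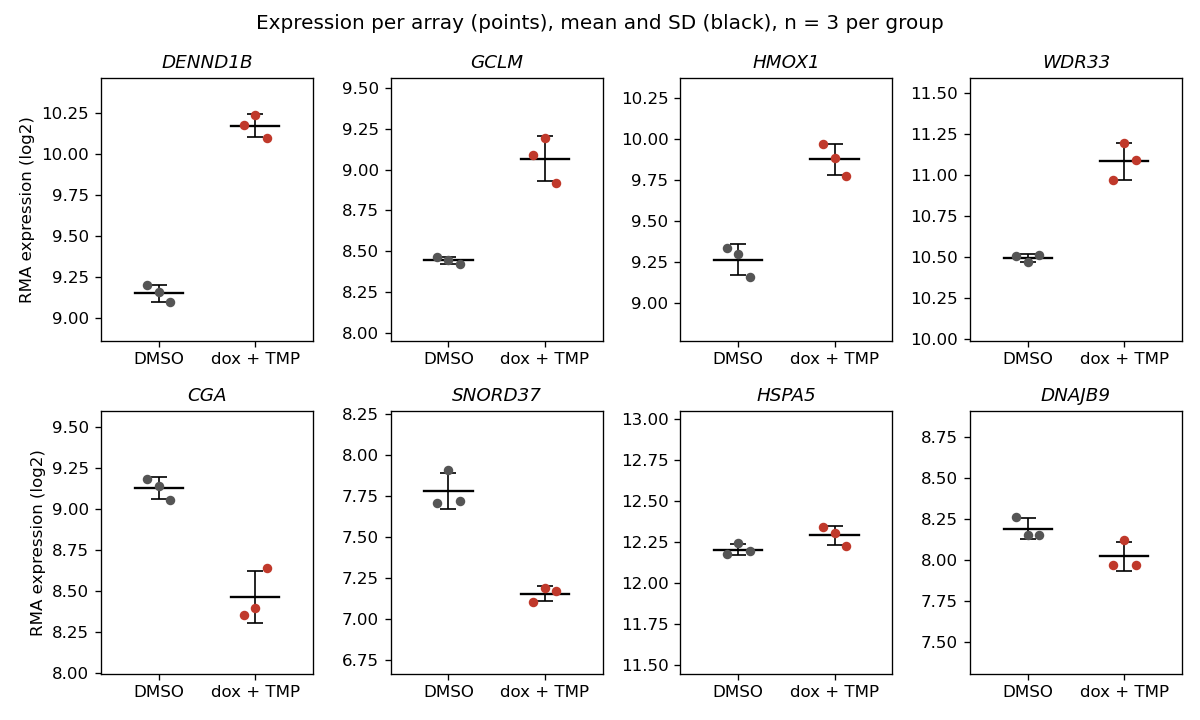
Log2 RMA expression on each array (points, y axis, each panel spanning the same range) with the group mean and SD (black; n = 3 arrays) for 8 genes with DMSO or with doxycycline and trimethoprim (dox + TMP). DENND1B, GCLM, HMOX1 and WDR33 lay higher and CGA and SNORD37 lower on every treated array, while HSPA5 and DNAJB9 did not pass the test (limma adjusted p of 0.401 and 0.181).

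CGA (probe set 8128001) measured 9.13 ± 0.07 with vehicle and 8.47 ± 0.16 with treatment (n = 3 arrays each), a limma difference of -0.66 with a standard error of 0.0775 and an adjusted p of 0.0133. Of the 12 largest falls among genes past the threshold, 8 were small nucleolar RNAs: SNORD34 at -0.65, SNORA49 at -0.63, SNORD37 at -0.63, SNORD105 at -0.51, SNORD46 at -0.51, SNORD55 at -0.49, SNORD50A at -0.45 and SNORD117 at -0.45. SNORD37 had the smallest p among them (adjusted p = 0.0108). The rest were TMEM126A, a mitochondrial inner membrane protein that takes part in the assembly of respiratory complex I, at -0.49 (adjusted p = 0.0108), the actin-like gene ACTBL2 at -0.48 and the kinesin KIF24 at -0.47. ACTBL2 belongs to the actin family, whose members are alike in sequence, so its value is uncertain.

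The unfolded protein response lists did not shift. Of the 21 measured XBP1s targets, which serve protein entry, folding and degradation in the endoplasmic reticulum, 0 passed the limma test over all genes, 0 passed adjusted over the list alone, and 3 had an unadjusted p under 0.05. Their median difference was 0.00 and the camera adjusted p was 0.976. All 21 intervals lay within 1.5-fold in either direction, the lowest bound being -0.33 and the highest 0.34. The margin of 1.5-fold bounds the size of a shift and does not separate shifted lists from others. All 29 intervals of the mitochondrial ribosome list, which lay lower in camera, also fell within it. DNAJB9, a co-chaperone, differed by -0.17 (95% interval -0.30 to -0.03), DNAJC3 by 0.19 (0.03 to 0.34) and SEC61B by -0.18 (-0.33 to -0.02), with adjusted p of 0.181, 0.183 and 0.212. Of the 15 ATF6 targets, 0 passed over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. Their median was -0.02, their mean 0.01 and the camera direction lower, so these differ in sign, with an adjusted p of 0.988. All 15 intervals lay within 1.5-fold (bounds -0.21 and 0.28). HSPA5, the chaperone BiP, differed by 0.09 (-0.03 to 0.20) and HSP90B1 by 0.10 (-0.03 to 0.23), and MANF by -0.09 (-0.21 to 0.04).

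Of the 27 measured PERK and ATF4 targets, the amino acid and integrated stress response, 0 passed over all genes, and 1 was higher and 1 lower adjusted over the list alone. Their median was -0.02 and the camera adjusted p 0.677, and all 27 intervals lay within 1.5-fold (bounds -0.46 and 0.53). DDIT3, the transcription factor CHOP, differed by -0.31 (standard error 0.0703, adjusted p = 0.0741), the cystine transporter gene SLC7A11 by 0.35 (0.0819, 0.078) and JDP2 by 0.16 (0.051, 0.145). Of the other fixed genes, PDIA4 differed by 0.06, SEL1L by 0.06, HERPUD1 by 0.11, XBP1 by -0.06, TRIB3 by 0.06, ASNS by -0.01 and TYMS by -0.04, and none passed the test. Of the 27 list members, 8 had an unadjusted p under 0.05.

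**Figure D2:**
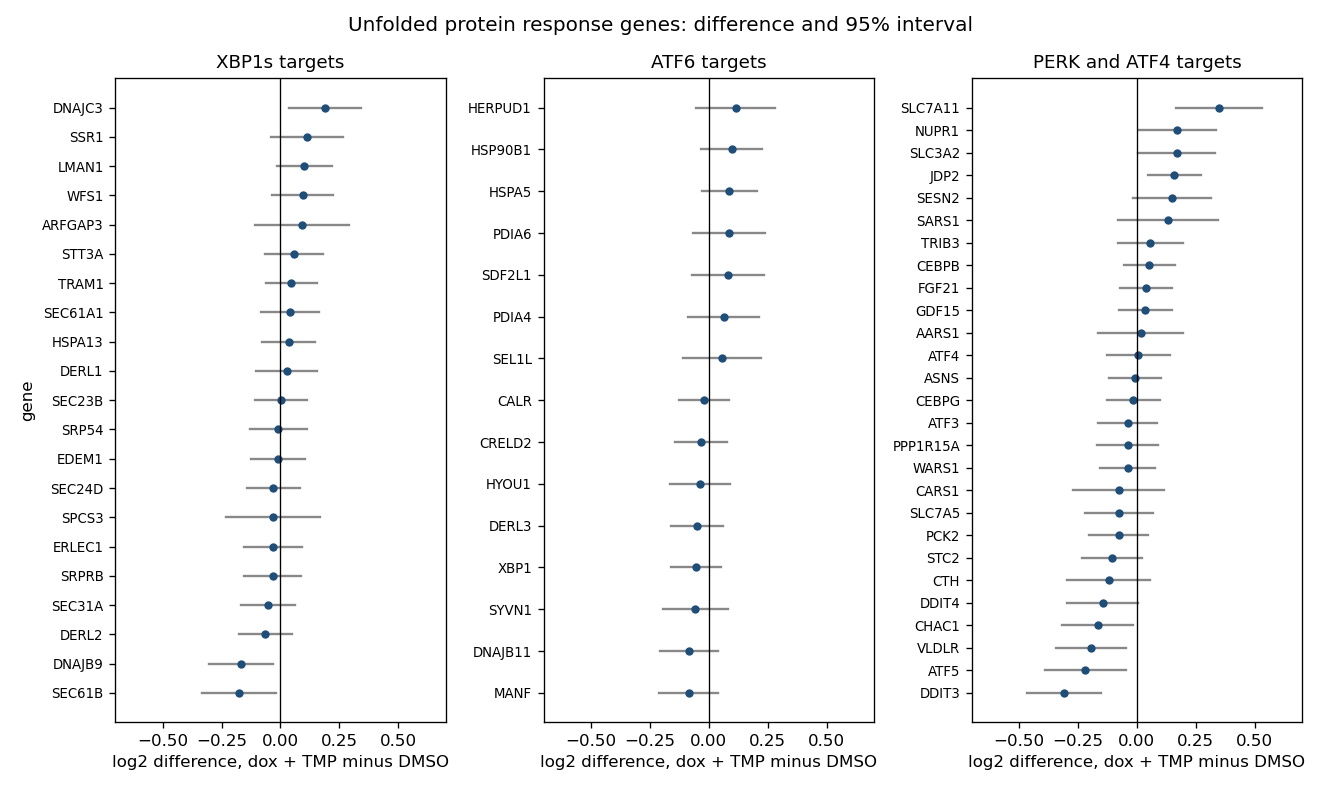
Log2 difference (x axis, doxycycline and trimethoprim minus DMSO, n = 3 arrays each) with its 95% interval from limma for each measured member (y axis) of the XBP1s, ATF6, and PERK and ATF4 target lists. The points scatter on both sides of 0, and the outermost bounds are -0.46 and 0.53.

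Among the other fixed lists, the NRF2 targets, the genes of the oxidative stress response, lay higher. Of 13 measured members 2, HMOX1 and GCLM, rose over all genes and 5 were higher adjusted over the list alone. The list median was 0.12 with a camera adjusted p of 0.000482, and the adjusted p = 0.194 with an estimated correlation. SLC7A11, shared with the PERK and ATF4 list, had the next smallest p, and 10 of the 13 members lay above 0.

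Lower values were found together in 5 lists. Of 191 small nucleolar and small Cajal body RNAs, 12 fell over all genes, 54 were lower and 1 was higher adjusted over the list alone, and the median was -0.13 (camera adjusted p = 2.90e-17; adjusted p = 0.14 with an estimated correlation). SNORD37, SNORD117 and SNORA50A (-0.44) had the smallest p. Of 42 nuclear genes of oxidative phosphorylation, 0 passed over all genes and 17 were lower adjusted over the list alone, with a median of -0.13 (camera adjusted p = 4.79e-11; adjusted p = 0.194 with an estimated correlation); NDUFA1 differed by -0.32, NDUFS7 by -0.29 and NDUFS4 by -0.36. UQCRH, a complex III gene outside the fixed list and chosen after its value was seen, fell by 0.38 (adjusted p = 0.0442). Of 29 mitochondrial ribosomal protein genes, 0 passed over all genes and 6 were lower adjusted over the list alone, with a median of -0.12 (camera adjusted p = 3.71e-08; adjusted p = 0.312 with an estimated correlation); MRPL15 differed by -0.27, MRPL48 by -0.24 and MRPS12 by -0.29. Of 30 histone genes of the replication-dependent class, H3C10 (-0.41) fell over all genes and 11 were lower adjusted over the list alone, with a median of -0.15 (camera adjusted p = 2.24e-08; adjusted p = 0.48 with an estimated correlation); H4C4 differed by -0.28 and H2AC8 by -0.30. Of 26 cytosolic ribosomal protein genes, 0 passed over all genes and 2, RPS24 (-0.28) and RPL22 (-0.21), were lower adjusted over the list alone, with a median of -0.08 (camera adjusted p = 1.63e-05; adjusted p = 0.611 with an estimated correlation); RPS20 differed by -0.21. RPS21, outside the fixed list and chosen after its value was seen, fell by 0.34 (adjusted p = 0.0442). Small nucleolar RNAs and histones come in families of near-identical copies, so single members of these lists are uncertain.

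Each of these 6 list medians had the same sign on all 3 treated arrays. The small nucleolar RNA median lay -0.14, -0.12 and -0.12 from the vehicle mean on treated replicates 1, 2 and 3, and the NRF2 median 0.12, 0.18 and 0.12. None of the 6 list calls held with an estimated correlation (0 lists), and fry, which does not compare a list with other genes, called 3, the small nucleolar RNA, oxidative phosphorylation and NRF2 lists.

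**Figure D3:**
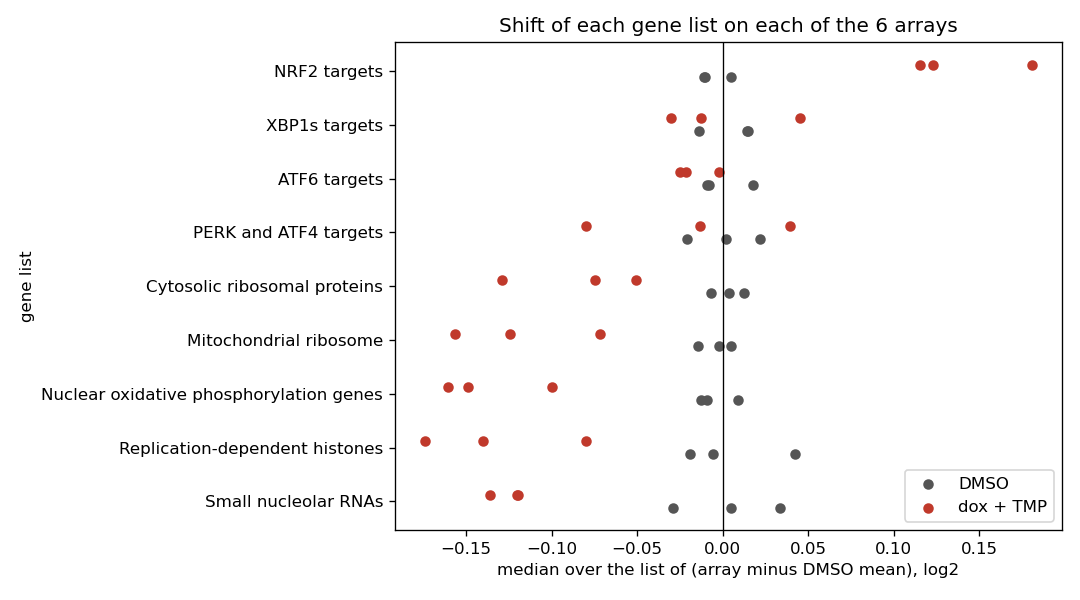
Median over each gene list of the log2 difference between an array and the vehicle mean (x axis), for 9 lists (y axis), with 1 point per array (n = 3 per group). The NRF2 targets lay between 0.12 and 0.18 on the treated arrays and the 5 lists below 0 between -0.17 and -0.05, while the 3 unfolded protein response lists lay between -0.08 and 0.05.

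The remaining 21 lists did not pass the camera test. The heat shock factor 1 targets came nearest, with a median of 0.06, 12 of 14 measured members above 0 and an adjusted p of 0.0616. The other 3 of the 17 fixed members, HSPA1A, HSPA1B and AHSA1, had no single-gene probe set, and HSPA1A and HSPA1B are the main inducible targets of this factor. Probe sets with several symbols were tested apart and are not named, and 12 of them passed. Whether any of these belong to the missing members was not examined, so the list test leaves the response of those members open. The camera adjusted p of the heat shock list was 0.0436 with the median of each array set to 0 and 0.00462 after quantile normalization once more. With trend and robust moderation it was 0.0318, and without vehicle replicate 2 it was 0.0281, so that call depended on the processing and on single arrays. In this list 1 member, the co-chaperone CHORDC1, was higher adjusted over the list alone (0.32), and HSPH1 differed by 0.19 and HSPA4L by 0.14. The metal-response list had a median of -0.03 and an adjusted p of 0.0949 (0.0281 without vehicle replicate 2 and 0.0238 without treated replicate 3, where it passed), and 4 of its 10 members were lower adjusted over the list alone, among them the metallothioneins MT1X (-0.37), MT1F (-0.42) and MT2A (-0.27), which are alike in sequence. Glycolysis genes had a median of 0.06, with 18 of 20 above 0 (camera adjusted p = 0.123). The camera adjusted p was 0.00473 after quantile normalization once more, 0.000636 without treated replicate 3 and 0.851 with an estimated correlation. GPI differed by 0.13, SLC2A1 by 0.12 and PFKFB3 by 0.10. In folate, one-carbon and serine metabolism, the pathway of the trimethoprim target, the median of 24 members was -0.02 (adjusted p = 0.388), and 1 member, GGH (-0.31), which hydrolyses folate polyglutamates, was lower adjusted over the list alone, while ALDH1L2 differed by -0.09 and ALDH1L1 by 0.14. Among 14 lysosome and autophagy genes, 3 were higher adjusted over the list alone, SQSTM1 (0.30), CTSD (0.23) and GABARAPL1 (0.27), with a list median of 0.01 (adjusted p = 0.388). Among 28 proteasome subunits, PSMD1 (0.21) and PSMD11 (0.29) were higher adjusted over the list alone, PSMA5 differed by -0.15, and the median was 0.00 (adjusted p = 0.793).

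Mitochondrial chaperones and proteases had a median of 0.00 and a mean of -0.05 with the camera direction lower (adjusted p = 0.363), hypoxia-inducible factor targets a median of 0.01 (0.976), p53 targets 0.02 (0.976), DNA replication genes -0.01 (0.988), mitosis genes -0.01 (0.746), and cholesterol synthesis genes -0.03 (0.388). For the hypoxia and p53 targets the camera direction was lower while median and mean lay above 0, and for DNA replication the mean (0.01) lay above 0. Immediate early genes had a median of -0.05 (adjusted p = 0.234, and 0.0376 without treated replicate 3), NF-kB targets 0.05 (0.947), interferon-stimulated genes -0.01 (0.724), and TGF-beta and BMP targets -0.03 (0.338). Over all genes, 0 members of any of these 10 lists passed in limma. Adjusted over the list alone, RELB (0.28) and ICAM1 (0.25) were higher among the NF-kB targets, and ACAT2 (-0.24) of cholesterol synthesis, IFIT1 (-0.28) of the interferon-stimulated genes and ID3 (-0.26) of the TGF-beta and BMP targets were lower. The other 6 of these lists had 0 such members. The 3 members with the smallest p were HSPE1 (-0.26), TIMM17A (-0.23) and CLPP (-0.13) for mitochondrial chaperones and proteases, INSIG2 (-0.10), EGLN1 (0.10) and EGLN3 (-0.09) for hypoxia, MDM2 (0.23), TP53I3 (-0.16) and SESN1 (-0.14) for p53. For DNA replication they were GINS1 (-0.18), CCNE2 (0.14) and RFC3 (0.14), for mitosis UBE2C (-0.22), AURKB (-0.12) and KIF11 (0.15), and for the immediate early genes KLF10 (-0.20), CCN1 (-0.17) and IER3 (-0.15). Beside the genes given above, FDPS differed by -0.15 and MSMO1 by 0.15, CXCL2 by -0.20, IRF7 by 0.12 and OAS2 by 0.12, and ID1 by -0.11 and TGFBI by 0.09.

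Markers of other cell types did not pass as lists on all 6 arrays, though the fibroblast markers passed without treated replicate 2 (adjusted p = 0.0454). The median was -0.05 for 8 epithelial markers (adjusted p = 0.388), 0.02 for 8 neuronal markers (0.976), 0.08 for 8 fibroblast markers (0.125), 0.10 for 6 leukocyte markers (0.388) and 0.05 for 6 endothelial markers (0.234). All 8 fibroblast markers lay above 0, PDGFRB at 0.16, COL3A1 at 0.16 and COL1A1 at 0.11. Adjusted over the list alone, CD14 (0.21) and CLDN5 (0.20) were higher and MAP2 (-0.22) was lower. The other members with the smallest p were the epithelial EPCAM (-0.09), KRT18 (0.11) and CLDN1 (-0.06), the neuronal STMN2 (0.14) and INA (0.12), the leukocyte CD3E (0.19) and LAPTM5 (0.25), and the endothelial CDH5 (0.10) and VWF (0.08).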

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

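Among the tests reported here, those of the level-matched random lists, of the gene spans, of the brighter small RNAs, of the small nuclear RNAs and of the splits for the count of genes were chosen only after the results were seen. A signal was found in rows of the table that the gene comparison leaves out: of 3019 probe sets with no gene symbol or with several, 17 passed an adjusted p of 0.05 in limma over all rows (12 with several symbols, 5 with none; 12 higher, 5 lower). Among the brightest were probe set 8118314, with 2 symbols, at a log2 difference of 0.63 (standard error 0.0886) and probe set 8118310, also with 2 symbols, at 0.42 (0.0598). No gene is named for them. Some of the 17 rows repeat the same signal, since probe sets 8178086 and 8179324 had the same values (difference 0.63). The count is therefore not one of separate transcripts.

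Lists of small nucleolar RNAs, histones, oxidative phosphorylation, the mitochondrial ribosome and cytosolic ribosomal proteins were lower together after treatment. All 5 list medians lay below the central 95% of 10000 random lists matched on level, which argues against a level-dependent difference in scale. Matching on level and genomic span left the histones at percentile 0.01. This cannot decide on a loss of short transcripts as their cause, since no detection call was made. Matched short genes with background signal only would not fall with such a loss. The same match left the cytosolic ribosomal proteins inside the random range (percentile 8.51), so a loss of short transcripts may account for them, and for oxidative phosphorylation and the mitochondrial ribosome (percentile at most 0.02) it stays open, since only 16.7% and 3.45% of their members have a span of up to 3000 bases and a long span can hold a short transcript. Other small RNAs, mostly microRNAs, had a median of 0.0224 (95% bootstrap interval 0.01 to 0.04). The 114 brighter ones, at a median level of 6.23 beside 6.24 for the box C/D RNAs, had 0.06 (0.04 to 0.08). These values cannot decide on a loss of all small RNA. Genes in general had a median of 0.07 at levels between 6 and 7, and the fall was larger in the 96 brighter small nucleolar RNAs (median level 9.01, -0.27). The 12 small nuclear RNAs had a median of -0.26 (-0.34 to -0.19). A smaller yield of small RNA, or of small nuclear and nucleolar RNA alone, in the treated preparations may be involved, and an effect of the treatment stays open beside it. The 10 splits of the 6 arrays are too few for a share under 0.05: the real split shifted 6 lists, 4 of the 10 including it shifted as many or more, and the highest other shifted 11.

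The NRF2 targets were higher after treatment. Level-matched random lists put the list median at percentile 99.99, against a difference in scale, and the 11 members other than HMOX1 and GCLM still gave a camera p of 0.0134 (p = 0.0605 with an estimated correlation), against those genes as the whole shift under the preset correlation. The design has 0 arrays with ligand and no transgene or the reverse, so the ligands and the expression of the fluorescent proteins cannot be told apart here. A mild oxidative stress response to one of them is a hypothesis that remains open.

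DENND1B had the largest rise. Its second probe set differed by 0.95 (95% interval 0.82 to 1.07), against a signal of a single probe set. The nearest measured genes in assembly GRCh38.p14 were ZBTB41 and CRB1 before DENND1B and C1orf53 and LHX9 after it. None of these neighbours had an upper 95% bound over 0.24, against transcription of the whole neighbourhood. ZBTB41 and CRB1 differed by 0.03 and 0.05, and C1orf53 and LHX9 by -0.21 and -0.24 (limma adjusted p = 0.117 and 0.0985). Hybridisation of a transgene transcript to both probe sets was not tested, as probe sequences were not used here, and an effect of the treatment stays open. For the count of genes, 1 of the 10 splits, the real one, gave as many as 61 and the highest other gave 0; 10 splits cannot give a share under 0.05.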

How the results depend on the processing

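Cyclic loess was chosen after the data were seen; all other alternatives were set before. The 61 genes kept their sign in every alternative fit compared gene by gene. These were trend and robust moderation, array weights, the mean of probe sets, quantile normalization, cyclic loess, the replicate block and each array left out. The 61 genes had been chosen on the same arrays, so the kept signs were nearly fixed in advance. The number past the threshold moved widely. Trend and robust moderation called 67 genes, 54 of them shared, the mean of probe sets 71 (60 shared), cyclic loess 53 (36 shared) and quantile normalization 41 (29 shared). Array weights called 2697 genes (1206 higher, 1491 lower), testing every row 30 higher ones, and the median of each array set to 0 gave 35 (23 lower). An adjusted p under 0.10 gave 669 (276 higher, 393 lower), and a minimum of 1.5-fold gave 8 (4 higher, 4 lower), fewer by construction. With the replicate block, 19 genes passed (7 higher, 12 lower), 18 of them shared. Same-numbered arrays had correlations of -0.08, -0.08 and -0.13, which gave no support for a pairing, though so few arrays cannot exclude one. Leaving out each array gave 1 to 1454 genes, 1 to 598 higher and 0 to 856 lower, and 6 to 10 lists, the highest without treated replicate 3. For the other alternatives the cause was not tested.

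The 6 list calls held under each alternative run for lists, except that an estimated correlation left 0 and fry left 3; testing every row and the other thresholds were run for the counts of genes only. Heat shock targets passed with array weights (0.0315), without the dimmer genes (0.00119) and after cyclic loess (0.00563), among others. They did not pass in camera with an estimated correlation (adjusted p = 0.611) or with fry (adjusted p = 0.146). The direction of lists near 0 turned without passing. For ATF6 targets, adjusted p was 0.99 with trend and robust moderation, 0.897 with array weights, 0.473 with the dimmer genes left out, 0.942 with the median set to 0, 0.426 after quantile normalization, 0.489 after cyclic loess, 0.981 with the replicate block and 0.927 with fry (0.759 to 0.952 over arrays left out, turned without vehicle replicate 2 and without treated replicate 3). XBP1s targets turned with array weights (0.955) and without replicate 2 of either group (0.62 to 0.986 over arrays left out), and PERK and ATF4 targets without treated replicate 3 (0.314 to 0.816 over arrays left out). With array weights, DNA replication (0.77) and NF-kB targets (0.897) turned. With the dimmer genes left out, hypoxia (0.567), p53 (0.487), DNA replication (0.424), mitosis (0.673), NF-kB (0.567) and interferon (0.995) turned, and with the median set to 0, DNA replication (0.942). After quantile normalization, hypoxia (0.568), p53 (0.597), DNA replication (0.493), mitosis (0.886), NF-kB (0.843), neuronal markers (0.843) and the gene ASNS (difference 0.0165) turned. After cyclic loess, hypoxia (0.622), p53 (0.664), DNA replication (0.438), mitosis (0.833), NF-kB (0.864), neuronal markers (0.864) and ASNS (0.0093) turned. With fry, hypoxia, p53 and DNA replication turned (0.976 each). Over arrays left out, adjusted p ran from 0.62 to 0.986 for hypoxia, 0.599 to 0.952 for p53, 0.595 to 0.952 for DNA replication, 0.388 to 0.889 for mitosis, 0.54 to 0.952 for NF-kB, 0.54 to 0.952 for the proteasome and 0.771 to 0.974 for neuronal markers, and the ASNS difference from -0.0253 to 0.0082. Signal over background limits the dim genes, for which no detection call was made.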

Other observations

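Among the tests below, the families, formed from gene symbols, their scaling checks and the small nuclear RNAs were chosen after the results were seen. Genes whose symbols start alike were grouped into 125 families of at least 15 genes, and 22 families passed an adjusted p of 0.05 with camera at its preset correlation. With an estimated correlation 0 passed (lowest adjusted p = 0.0833). Collagen genes stood higher: 41 of 44 lay above 0 with a median of 0.13 (adjusted p = 5.02e-08; adjusted p = 0.778 with an estimated correlation), although 0 of them passed the gene test and 23 had an unadjusted p under 0.05. Their median lay 0.16, 0.07 and 0.15 from the vehicle mean on treated replicates 1, 2 and 3. Of the 22 families, 3 lay inside the central 95% of random lists of genes with the same levels. After cyclic loess 39 of 44 lay above 0, with a median of 0.10. The late cornified envelope genes (LCE), expressed in skin, lay above 0 in 17 of 17 cases with a median of 0.13, and the POU family of transcription factors in 16 of 17 with a median of 0.11, and after cyclic loess in 16 and 14 cases (adjusted p = 0.778 with an estimated correlation for each). Among random lists of the same levels the collagen, LCE and POU medians lay at percentiles 100, 99.9 and 99.5, but these families were picked out of 125 for their shift and the percentiles make no allowance for that. Genes in general shifted with level: the 2474 with a mean between 6 and 7 had a median of 0.07, the 2847 between 7 and 8 one of 0.03 and the 3125 between 8 and 9 one of -0.03.

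Large mitochondrial ribosomal subunit genes (MRPL) were lower in 44 of 48 cases, with a median of -0.15 (adjusted p = 4.74e-12; adjusted p = 0.778 with an estimated correlation), and the small subunit genes (MRPS) in 24 of 26, with a median of -0.13; these families include the members of the fixed list. The same counts, 44 and 24, were found after quantile normalization and after cyclic loess. Spliceosomal small nuclear RNAs were lower in 11 of 12 cases, also after cyclic loess (median -0.25); RNU4ATAC, a part of the minor spliceosome that was chosen after its value was seen, differed by -0.67 (standard error 0.147, limma adjusted p = 0.0731). Small Cajal body RNAs (SCARNA, 16 genes) had a median of -0.23, box C/D RNAs (SNORD, 114) one of -0.11 and box H/ACA RNAs (SNORA, 61) one of -0.13.

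Most small nucleolar RNAs are cut out of introns of host genes, so a fall in host transcripts was tested as a hypothesis, with a prediction set before the result. Hosts were assigned by position alone, without the strand. The 76 measured host genes had a median of -0.0136 (95% bootstrap interval -0.03 to 0.01) and 0 of them fell past the threshold, while the 98 small nucleolar RNAs inside them had a median of -0.18. The host transcripts therefore did not fall by the amount seen in the small RNAs. Transcript levels do not measure transcription, so a fall in host transcription stays open. Of the small nucleolar RNAs named above for the largest falls, SNORD37 and SNORA49 had a measured host. The others, such as SNORD34 and SNORD46, had none. The 96 brighter small nucleolar RNAs had a median of -0.27 and the 95 dimmer ones one of -0.05.

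The first principal component held 41.2% of the variance and separated the groups, with scores from -8.29 to -6.59 for vehicle arrays and from 3.40 to 12.2 for treated ones. The second held 29.8% and set treated replicate 2 (9.26) against treated replicate 3 (-13.5). The list means were larger in the real split than in any of the other splits of the 6 arrays for all 6 shifted lists (exact p = 0.1 each, 2-sided, the smallest the design allows). The same held for 6 lists that did not pass, among them the heat shock factor 1 targets and the fibroblast markers, so this does not set the shifted lists apart.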
